A study of Mus musculus with 69 samples.

How the data were processed

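Livers of mice on a high-fat diet were sampled every 3 h over 24 h in 3 groups (control, JNK7a and JNK7b). Per the labels' protocols, total RNA was purified with RNeasy columns and DNase treatment, polyadenylated RNA was made into libraries, and these were sequenced as paired reads of 150 bases on a NovaSeq6000. Per the submitters' processing notes, cutadapt and Salmon were used, with the genome build mm10 named; their versions and settings, the annotation and how the recombinases were delivered are not given in the sources used here, nor is the light schedule. Salmon assigns reads to transcripts and shares reads that match several of them, so near-identical genes (Mup, Cyp2b, Cyp2c, Cyp2d, Slc22a, immunoglobulin, globin and Saa genes) are uncertain one by one.

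The authors deposited a table of estimated counts per gene, named as scaled by length from transcript abundance, so they are not whole numbers and were rounded here before any test. The authors also deposited a table of TPM (transcript abundance scaled for length and library total), used here only for alternatives and for the share of mitochondrial RNA, which lay between 10.5% and 16.0%. Each table had 55487 lines, of which 234 shared a symbol with another line; these were summed to 55367 gene symbols, and 25517 genes had no count in any library. All sample columns were used. Gene positions come from the GENCODE annotation of mm10. Totals were 26.8 to 48.6 M counts per library (M, mega; median 32.7 M), and the common biological coefficient of variation was 0.248, so the spread between libraries, rather than counting error, limits the precision of all but the low genes.

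Groups, clock hours and replicate numbers were taken from the labels. The replicate pairs of each group and hour were checked for libraries deposited more than once: over 69 pairs the chi-square per degree of freedom lay between 21.7 and 259, so no pair agreed within sampling noise and every library was counted. The replicate numbers were checked for pairing between groups and did not pair the samples.

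Genes were filtered with edgeR's filterByExpr by group, which left 14398, and scaled with TMM factors. The 3 comparisons of groups used edgeR's quasi-likelihood test (robust) with 1 coefficient for each of the 24 cells of group and clock hour, all 69 libraries in the fit and 45 residual degrees of freedom. Each contrast was the mean over the 8 clock hours with equal weight. Rhythm was tested with a cosine and a sine of 24 h period per group (60 residual degrees of freedom), jointly within a group and as the difference between groups. P-values were adjusted by Benjamini-Hochberg, and a gene is called, or said to have risen or fallen, at an adjusted p below 0.05. Log2 CPM, used for rhythm amplitudes, peak hours and scores, had a prior count of 2. Fold changes came from the quasi-likelihood fit with its own default prior count. Those of genes with a cell at 0 depend on that prior, so CPM is given for them, except for Klrb1c. The standard error of a fold change was worked back from its test. It is the absolute log2 fold change over the square root of the F value, and so is approximate. Gene lists were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 35 of 36 lists with at least 5 measured members, and called members were counted after adjustment over all genes and over the list alone. The lists were core clock, PPARα and fatty acid oxidation, de novo lipogenesis, cholesterol synthesis, bile acids, gluconeogenesis, hepatokines, lipid droplets, AP-1, JNK pathway, splicing regulators, unfolded protein response, acute phase, interferon, extracellular matrix, NRF2, CAR and PXR, AhR, male-biased and female-biased genes, heat shock, amino acids, cell cycle, oxidative phosphorylation, and markers of pericentral and periportal hepatocytes and of 10 other cell types or tissues.

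The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Under that rule a gene can be named if its symbol is not a provisional one (Gm with digits, Rik or -ps names) and its mean is at least 1 CPM. Named genes are, per comparison, the 8 largest rises and 8 largest falls among called genes with the same sign at 7 or more of the 8 clock hours, and per list up to 4 called members with the smallest p. Mapk8, Mapk9 and all core clock genes are named whatever their values, as are up to 8 genes per difference of rhythm. Exceptions were allowed for the 2 most expressed members of a list without calls and for markers that stand apart in single libraries. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

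The alternatives were median-ratio size factors, no filter, a mean of at least 1 CPM, DESeq2, limma voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), an additive design, only the groups of a comparison, clock hour as a factor of 8 levels, 24 h with 12 h cosines, a replicate block, and leaving out each library or each clock hour. Fits without 2 doubted libraries, over 4 of the 8 clock hours, and of the 12 h component alone were added after seeing the data. On log2(TPM + 1) the changes of low genes are understated. The tests were tried on simulated data. For JNK7a against control, on 14171 genes, 90% of 100 genes changed 1.5-fold and 99% of 100 changed 2-fold were called, with 14 of 13941 unchanged genes. For rhythm, on 14204 genes, log2 amplitudes of 0.5 and 1 were called in 84% and 100% of 100 genes each in control and in 78% and 94% in JNK7a. Simulated genes were independent and followed the dispersion trend, and changed genes had a mean above 1 CPM, so real shares may be lower. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, matplotlib 3.10.9 and the R package data.table, version 1.17.8.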

Results

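Liver RNA was sequenced from C57/Bl6J mice kept on a high-fat diet (HFD), in which the c-Jun N-terminal kinases (JNK) of hepatocytes differed between 3 groups. JNK1 and JNK2, encoded by Mapk8 and Mapk9, are stress-activated kinases whose transcripts carry either of a pair of alternative exons, 7a or 7b. The groups were control, JNK7a and JNK7b, named after these spliceoforms, and the sources used here do not say in more detail which transcripts each group makes, nor whether a name gives the spliceoform kept or lost. The labels tie control to green fluorescent protein (GFP), JNK7a to the recombinase Cre and JNK7b to the recombinase FLPo, so each comparison also differs in that protein. Livers were taken every 3 h over 24 h, at clock hours 2, 5, 8, 11, 14, 17, 20 and 23, which gave 24 control, 22 JNK7a and 23 JNK7b libraries with 2 to 4 libraries per group and hour. Totals ran from 26.8 to 48.6 M estimated counts per library (M, mega; median 32.7 M), and 14398 genes were tested. The labels do not state that the libraries are separate animals, so p-values measure the spread between these samples. Expression of the Y-linked gene Ddx3y lay between 44.3 and 82.9 CPM (counts scaled to the library total) and Xist reached at most 2.06 CPM, so every library had the pattern of a male liver.

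The genes of the targeted kinases were examined first. Mapk8 (chromosome 14, 33377898 to 33447158, minus strand, mm10) was expressed in all 69 libraries, at 17.8 ± 2.29 CPM in control (SD, n = 24), 14.6 ± 3.28 CPM in JNK7a (n = 22) and 17.7 ± 2.15 CPM in JNK7b (n = 23). Mapk9 (chromosome 11, 49846751 to 49886421, plus strand, mm10) was at 49.9 ± 10.5, 41.0 ± 4.56 and 56.7 ± 7.91 CPM. In JNK7a, Mapk8 had a log2 fold change against control of -0.28 ± 0.07 (standard error, adjusted p = 0.00212) and Mapk9 of -0.27 ± 0.07 (adjusted p = 0.00503). In JNK7b neither gene passed the test against control (-0.01 ± 0.07, adjusted p = 0.968 and 0.18 ± 0.07, adjusted p = 0.103). For Mapk9, JNK7b against control was called by limma voom (adjusted p = 0.00977), without clock hour 5 (adjusted p = 0.0165) and without control 8 h replicate 3 and JNK7b 5 h replicate 2 (log2 0.17, adjusted p = 0.0344), so this stays open. Control 8 h replicate 3 had the Mapk9 value of neither group, 14.1 CPM, below the 28.9 to 47.3 CPM of JNK7a. Without it alone, Mapk9, JNK7a against control kept its call (log2 -0.32). Both were higher in JNK7b than in JNK7a, with log2 fold changes of 0.27 ± 0.07 (adjusted p = 0.00330) and 0.45 ± 0.08 (adjusted p = 7.5e-06). A gene-level count adds both spliceoforms, so these values check neither the isoforms nor the group labels.

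To find how JNK7a livers differed from control livers over the day, JNK7a libraries (n = 22) were compared with control libraries (n = 24) at matched clock hours. The lipid droplet genes Cidec and Plin4 and the fatty acid transporter gene Cd36 were lower in JNK7a. Cidec, whose protein promotes the fusion of lipid droplets, was at 3.47 ± 2.59 CPM in JNK7a and 40.8 ± 25.8 CPM in control (SD), a log2 fold change of -3.55 ± 0.33 (standard error, adjusted p = 1.6e-11). Plin4, a lipid droplet coat protein gene, fell from 34.6 ± 24.5 to 4.49 ± 1.92 CPM (log2 -2.74 ± 0.22, adjusted p = 4.2e-13). Cd36, a fatty acid transporter gene, fell from 190.2 ± 68.7 to 39.5 ± 27.7 CPM (log2 -2.31 ± 0.20, adjusted p = 3.0e-12). In the other direction, Igfbp2, which encodes a circulating insulin-like growth factor binding protein, rose from 129 ± 37.5 to 328 ± 72.6 CPM (log2 1.38 ± 0.10, adjusted p = 1.6e-14). Each of these 4 differences had the same sign at all 8 clock hours.

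**Figure D1:**
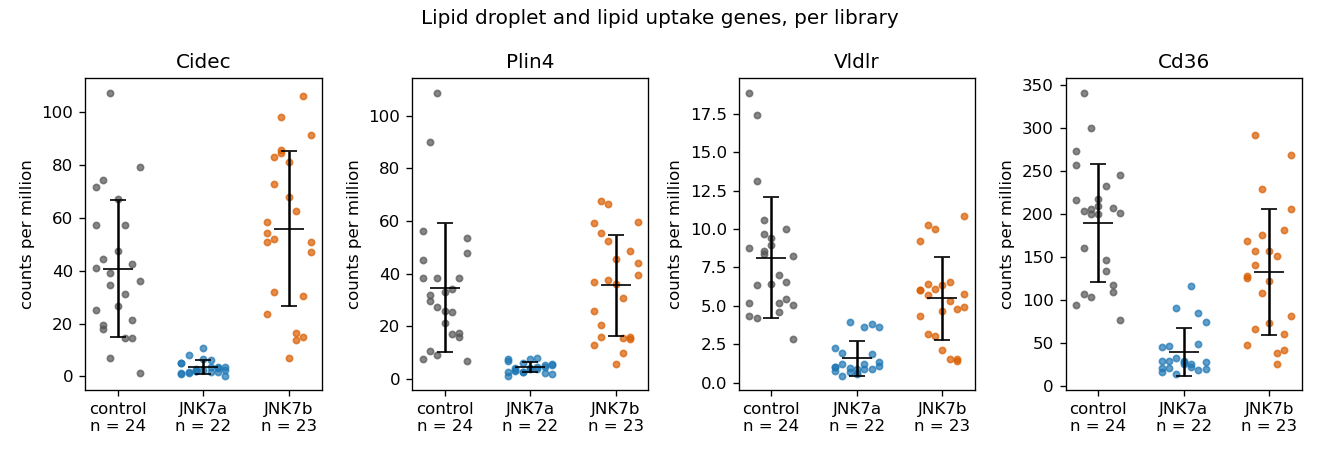
Expression in CPM (vertical axes) of Cidec, Plin4, Vldlr and Cd36 in each library by group; points are single libraries and bars are the mean ± SD (control n = 24, JNK7a n = 22, JNK7b n = 23). The JNK7a means lie below the control means for all 4 genes, for example 3.47 ± 2.59 against 40.8 ± 25.8 CPM for Cidec.

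In total 1391 genes were higher and 1593 lower in JNK7a than in control, and 161 of the higher and 145 of the lower genes differed at least 2-fold. The largest rises by the rule for named genes were those of the axonemal dynein gene Dnaic1 (log2 5.41 ± 0.45, 3.37 ± 2.32 against 0.125 ± 0.236 CPM), the immunoglobulin genes Ighg1, Ighg2c, Igkv1-135, Igkv10-96 and Ighg2b (log2 3.39 to 5.40), the steroid dehydrogenase gene Hsd3b5 and Lrp2, the gene of the endocytic receptor megalin. Hsd3b5 had a log2 fold change of 3.34 ± 0.51 (adjusted p = 1.7e-06) and Lrp2 of 2.87 ± 0.23 (adjusted p = 4.2e-13). The largest falls, beside Cidec, were those of the peroxisomal oxidase gene Hao2 (log2 -4.11 ± 0.36), the transporter genes Slc22a27 (log2 -3.64 ± 0.32) and Slc22a29 (log2 -3.17 ± 0.28) and Cfd, which encodes adipsin (log2 -3.43 ± 0.33). Dusp8, which encodes a phosphatase of JNK and p38, also fell (log2 -3.27 ± 0.29). Cidea, a relative of Cidec, had a log2 fold change of -4.13 ± 0.55 (adjusted p = 1.2e-07 with edgeR, but not called by limma voom). The cytochrome P450 gene Cyp2b13, at 0.130 ± 0.185 CPM in JNK7a and 2.93 ± 4.38 CPM in control, was also called, but not without control 11 h replicate 2 (log2 -4.39, adjusted p = 0.0685, from 2.4e-05 to 0.0685 over the fits that left out 1 library). Immunoglobulin, Slc22a and Cyp2b genes have near-identical relatives, among which counts are uncertain.

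Fatty acid oxidation and lipid storage genes fell together. Of the 32 measured targets of the fatty acid sensor PPARα and genes of fatty acid oxidation, 24 fell (25 adjusted over the list alone). The PPARα list had limma camera adjusted p = 6.2e-23, and adjusted p = 0.0331 with an estimated correlation. Among the genes that fell were the thioesterase genes Acot2 (log2 -1.64 ± 0.16) and Acot1 (log2 -0.92 ± 0.09) and the peroxisomal oxidation gene Acaa1b (log2 -0.71 ± 0.07). Of 23 lipid droplet and steatosis markers, 16 fell and 1 rose (17 and 1 adjusted over the list alone), including Mogat1, a triglyceride synthesis gene (log2 -2.81 ± 0.24), and the lipoprotein receptor gene Vldlr (log2 -2.42 ± 0.22), while the lipoprotein lipase gene Lpl was the member that rose (log2 1.07 ± 0.14). The lipid droplet list had adjusted p = 1.8e-15, and adjusted p = 0.0244 with an estimated correlation. De novo lipogenesis genes fell in 8 of 23 cases (8 adjusted over the list alone), with the desaturase gene Scd1 (log2 -1.16 ± 0.23) and the elongase gene Elovl5 (log2 -0.74 ± 0.12) as examples. The lipogenesis list had adjusted p = 2.0e-04, but adjusted p = 0.502 with an estimated correlation. Cholesterol synthesis genes moved the other way, with 13 of 25 higher and 1 lower (14 and 1 adjusted over the list alone), among them Hsd17b7 (log2 0.70 ± 0.11). The cholesterol list had adjusted p = 6.3e-06, but adjusted p = 0.505 with an estimated correlation.

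Genes known to differ between male and female mouse liver separated by sex bias. Of 29 measured male-biased genes, 23 were higher in JNK7a (26 higher and 1 lower adjusted over the list alone), among them the oxysterol hydroxylase gene Cyp7b1 (log2 1.66 ± 0.17), the organic anion transporter gene Slco1a1 (log2 1.63 ± 0.23) and the major urinary protein genes Mup20 (log2 1.40 ± 0.13) and Mup21 (log2 1.48 ± 0.17). The male-biased list had adjusted p = 6.2e-23, but adjusted p = 0.0583 with an estimated correlation. Of 24 female-biased genes, 14 were lower and 1 higher (17 and 2 adjusted over the list alone), among them Hao2, Slc22a27 and the cytochrome P450 gene Cyp2b9 (log2 -2.79 ± 0.42). The female-biased list had adjusted p = 3.4e-13, and adjusted p = 0.0331 with an estimated correlation. Mup and Cyp2b genes have near-identical relatives, so single members are uncertain.

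Interferon response genes were higher in JNK7a, in 23 of 30 cases (25 adjusted over the list alone). The interferon list had adjusted p = 8.9e-17, and adjusted p = 0.0331 with an estimated correlation. Members that rose included the transcription factor gene Irf7 (30.8 ± 6.60 against 17.8 ± 3.02 CPM, log2 0.79 ± 0.08), Usp18, which limits interferon signalling (log2 0.98 ± 0.11), the antiviral sensor gene Oas1a (log2 0.90 ± 0.11) and the antiviral membrane protein gene Bst2 (log2 0.58 ± 0.06). Immune cell markers were higher in the same libraries. T and NK cell markers were higher in 9 of 16 cases (11 adjusted over the list alone), such as Cd8a (log2 2.24 ± 0.38) and the chemokine gene Ccl5 (log2 0.98 ± 0.24). The T and NK cell list had adjusted p = 2.0e-05, but adjusted p = 0.148 with an estimated correlation. B and plasma cell markers were higher in 4 of 13 cases (5 adjusted over the list alone), such as Igkc (72.6 ± 57.7 against 14.8 ± 23.7 CPM) and the antibody joining chain gene Jchain (log2 1.82 ± 0.28). The B cell list had adjusted p = 6.1e-05, but adjusted p = 0.163 with an estimated correlation. Kupffer cell and macrophage markers were higher in 3 of 23 cases (3 adjusted over the list alone), the clearest being Lpl, which the lipid droplet list also holds. Over all genes 1391 of 14398 were called higher, so this count lies near the share over all genes. The Kupffer cell list had adjusted p = 0.00263, but adjusted p = 0.505 with an estimated correlation.

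Other lists that passed the test were smaller shifts. Oxidative phosphorylation genes were lower in 19 of 37 cases (25 adjusted over the list alone), for example Sdha (log2 -0.15 ± 0.03). The oxidative phosphorylation list had adjusted p = 9.1e-09, but adjusted p = 0.490 with an estimated correlation. Gluconeogenesis and glucose handling genes were lower in 8 of 23 cases (9 lower and 2 higher adjusted over the list alone), including the pyruvate carboxylase gene Pcx (log2 -0.42 ± 0.05). The gluconeogenesis list had adjusted p = 6.1e-04, but adjusted p = 0.0583 with an estimated correlation. Bile acid genes were higher in 8 and lower in 3 of 23 cases (9 and 3 adjusted over the list alone), with the muricholic acid synthesis gene Cyp2c70 (log2 1.19 ± 0.12) and the bile salt export pump gene Abcb11 (log2 0.38 ± 0.04) higher. The bile acid list had adjusted p = 9.8e-04, but adjusted p = 0.107 with an estimated correlation. Genes of the unfolded protein and integrated stress response were higher in 9 and lower in 2 of 26 cases (10 and 2 adjusted over the list alone), among them the transcription factor gene Xbp1 (log2 0.44 ± 0.06). The unfolded protein list had adjusted p = 0.00219, but adjusted p = 0.502 with an estimated correlation.

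The remaining lists did not pass the test in this comparison, although single members did. AP-1 and immediate early genes were 1 higher and 8 lower of 25 measured, 1 and 8 adjusted over the list alone, adjusted p = 0.0816, and the called ones included Jun, whose protein JNK phosphorylates (log2 -1.3 ± 0.17), and Jund (log2 -0.65 ± 0.07). Counts for the other pathway lists, in the same order, were as follows. JNK pathway components had 1 higher and 4 lower of 17, 1 and 5, 0.185, splicing regulators 1 higher and 2 lower of 11, 1 and 2, 0.907, hepatokines and circulating factors 7 higher and 5 lower of 24, 9 and 6, 0.320, and the core clock 0 higher and 2 lower of 19, 0 and 2, 0.421. Acute phase and NF-kB genes had 8 higher and 2 lower of 28, 8 and 2, 0.133, extracellular matrix genes 1 higher and 3 lower of 24, 1 and 3, 0.117, NRF2 and glutathione genes 6 higher and 2 lower of 21, 8 and 4, 0.226, CAR and PXR xenobiotic genes 7 higher and 7 lower of 24, 7 and 9, 0.746, and AhR targets 1 higher and 1 lower of 7, 1 and 1, 0.328. Heat shock genes had 2 higher and 0 lower of 20, 1 and 0, 0.320, amino acid and urea genes 3 higher and 4 lower of 24, 3 and 4, 0.756, and cell cycle genes 1 higher and 2 lower of 31, 0 and 0, 0.251.

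Among zonation and cell type markers that did not pass as lists, the counts in the same order were 7 higher and 4 lower of 21, 7 and 4, 0.226 for pericentral and 6 higher and 2 lower of 21, 8 and 2, 0.133 for periportal hepatocytes, 0 higher and 1 lower of 20, 0 and 0, 0.759 for endothelial cells, 1 higher and 0 lower of 14, 1 and 0, 0.320 for cholangiocytes and 2 higher and 3 lower of 7, 2 and 3, 0.308 for adipocytes. Neutrophil markers (6 measured, adjusted p = 0.495), stellate cell markers (19 measured, adjusted p = 0.590) and red blood cell markers (8 measured, adjusted p = 0.797) had 0 members called by edgeR, with 1, 1 and 2 at an unadjusted p below 0.05. DESeq2 called 0 in each (1, 1 and 1 unadjusted) and limma voom 1, 0 and 0 (1, 2 and 1 unadjusted). Of the pancreas and muscle markers only 1 was measured, the elastase gene Cela1 (log2 0.46 ± 0.11), so that list was not tested. The median, mean and test differed in sign for the splicing regulator, CAR and PXR and adipocyte lists.

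These counts come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and list p-values from limma camera adjusted over 35 lists, of which 14 passed with the preset correlation and 4 with an estimated one. On the deposited TPM, tested with limma on log2(TPM + 1), the split of called genes was 703 higher and 2410 lower. The share of higher calls was 46.6% in the counts and 22.6% in TPM, where both the values and the test differ. The median log2 change over all genes was 0.0035 in the counts and -0.044 in TPM, so the TPM split includes an offset of the whole scale. Median-ratio size factors and DESeq2 gave 45.7% and 45.8%. Control 8 h replicate 3 had JNK7a-like values of several of these genes (Cidec at 1.21 CPM and Plin4 at 6.70 CPM), as did JNK7b 5 h replicate 2 (Cidec at 7.15 CPM). Without both libraries, an alternative chosen after seeing the data, 1388 genes were higher and 1634 lower, and 2848 of the 2984 calls remained.

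To find how JNK7b livers differed from control livers, JNK7b libraries (n = 23) were compared with control libraries (n = 24) in the same way. Interferon response genes were higher in JNK7b. Irf7 rose from 17.8 ± 3.02 to 44.6 ± 18.5 CPM (SD; log2 1.15 ± 0.08, standard error, adjusted p = 7.5e-16) and Usp18 from 5.45 ± 1.44 to 17.1 ± 9.74 CPM (log2 1.44 ± 0.11, adjusted p = 5.8e-14). Cyp2b10, a classical target of the xenobiotic receptor CAR, was at 15.0 ± 13.8 CPM against 1.83 ± 1.71 CPM (log2 2.40 ± 0.30, adjusted p = 4.1e-08). Igfbp2 was at 246 ± 73.5 against 129 ± 37.5 CPM (log2 0.94 ± 0.10, adjusted p = 9.2e-10). Cidec, which fell in JNK7a, was at 55.9 ± 29.3 CPM in JNK7b and did not pass the test against control (log2 0.52 ± 0.27, adjusted p = 0.220).

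In total 949 genes were higher and 986 lower in JNK7b than in control, 147 and 46 of them at least 2-fold. The largest rises by the rule for named genes, beside Cyp2b10, were those of Dnaic1 (log2 3.86 ± 0.48, adjusted p = 3.9e-08), the cytochrome P450 gene Cyp2d12 (log2 3.00 ± 0.26, adjusted p = 1.5e-12) and the proton pump subunit gene Atp6v0e2 (log2 2.25 ± 0.16, adjusted p = 5.0e-16). The immunoglobulin genes Ighg2c (log2 3.37 ± 0.51) and Ighg2b (log2 2.73 ± 0.44) rose too. Ighg1 (log2 3.82 ± 0.76) lost its call without JNK7b 5 h replicate 2 (log2 2.65, adjusted p = 0.522, from 8.8e-05 over the fits that left out 1 library) and with limma voom. Tmeff2, a transmembrane protein gene at 3.74 ± 4.40 CPM in JNK7b and 0.0911 ± 0.214 CPM in control, was called too. It was not called without JNK7b 14 h replicate 1 or 5 h replicate 2, though its log2 change was still 3.74 and 3.84. The lowest adjusted p over the fits that left out 1 library was 2.6e-07. Each of those 2 fits left 1 JNK7b library at that hour, where a cell without counts can void the test. They therefore do not decide whether the call rests on these libraries. The largest falls were those of Cfd (log2 -1.90 ± 0.29, adjusted p = 4.4e-06), Cyp2a22 (log2 -1.59 ± 0.35), the proton pump subunit gene Atp6v0d2 (log2 -1.46 ± 0.30) and the keratin gene Krt23 (log2 -1.36 ± 0.24). Falls were also found for the G protein gene Gna14 (log2 -1.32 ± 0.20) and Fam83f (log2 -1.32 ± 0.25). Obp2a fell (log2 -1.32 ± 0.35) but was not called by limma voom or without clock hour 20 (adjusted p up to 0.157 over the alternatives).

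Of 30 interferon response genes, 25 were higher (28 adjusted over the list alone), including Ifi44 (log2 1.29 ± 0.13) and Oasl1 (log2 0.90 ± 0.10). The interferon list had limma camera adjusted p = 1.7e-38, and adjusted p = 7.6e-04 with an estimated correlation. Immune cell markers moved with them. Kupffer cell and macrophage markers were higher in 6 of 23 cases (12 adjusted over the list alone), including Mpeg1 (log2 0.67 ± 0.11). The Kupffer cell list had adjusted p = 5.1e-07, but adjusted p = 0.50 with an estimated correlation. T and NK cell markers were higher in 4 and lower in 1 of 16 cases (5 and 1 adjusted over the list alone), with Cd8a higher (log2 2.20 ± 0.38). The T and NK cell list had adjusted p = 2.5e-04, but adjusted p = 0.50 with an estimated correlation. B and plasma cell markers were higher in 3 of 13 cases (3 adjusted over the list alone). The B cell list had adjusted p = 0.0194, but adjusted p = 0.852 with an estimated correlation, and its call was lost without control 2 h replicate 1 (adjusted p = 0.196) or JNK7b 5 h replicate 2 (adjusted p = 0.0745), with 1.3e-04 to 0.196 over the fits that left out 1 library, and without clock hour 14 or 20 or on log2(TPM + 1).

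Metabolic lists changed as well. Cholesterol synthesis genes were higher in 15 of 25 cases (21 higher and 1 lower adjusted over the list alone), including the sterol demethylase gene Cyp51 (log2 0.78 ± 0.17), Dhcr7, the last step of cholesterol synthesis (log2 0.54 ± 0.12), and Sc5d (log2 0.38 ± 0.07). The cholesterol list had adjusted p = 1.5e-12, but adjusted p = 0.50 with an estimated correlation. Male-biased genes were higher in 12 and lower in 1 of 29 cases (13 and 1 adjusted over the list alone), including Mup20 (log2 1.28 ± 0.13) and the complement gene C6 (log2 0.80 ± 0.12). The male-biased list had adjusted p = 6.0e-06, but adjusted p = 0.852 with an estimated correlation. Oxidative phosphorylation genes were lower in 7 and higher in 1 of 37 cases (12 and 2 adjusted over the list alone), for example Cox7b (log2 -0.18 ± 0.04). The oxidative phosphorylation list had adjusted p = 2.5e-04, but adjusted p = 0.933 with an estimated correlation. Cidea, which was nearly absent in JNK7a, was higher in JNK7b than in control (17.4 ± 13.8 against 5.14 ± 5.35 CPM, log2 2.15 ± 0.39, adjusted p = 7.0e-05).

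A further 3 lists passed the test less firmly. Amino acid and urea metabolism genes were lower in 5 and higher in 1 of 24 cases (7 and 1 adjusted over the list alone), with the methyltransferase gene Gnmt lower (log2 -0.49 ± 0.09). The amino acid list had adjusted p = 0.00966, but adjusted p = 0.933 with an estimated correlation, and its call was lost without clock hour 8 (adjusted p = 0.420, from 2.0e-05 over the alternatives). CAR and PXR xenobiotic genes were lower in 8 of 24 cases (9 lower and 1 higher adjusted over the list alone), among them the receptor gene Nr1i3 (log2 -0.48 ± 0.08) and Cyp2c37 (log2 -0.82 ± 0.16), while Cyp2b10 was the member that rose. The CAR list had adjusted p = 0.0326, but adjusted p = 0.852 with an estimated correlation. That list lost its call without any 1 of 8 single libraries (adjusted p 0.0121 to 0.0630 over all of them), without clock hour 14 or 23 (up to 0.170) and with the stricter filter. Cell cycle genes were higher in 3 of 31 cases (3 adjusted over the list alone), including Ccnd1, the gene of cyclin D1 (log2 0.64 ± 0.13). Over all genes 949 of 14398 were called higher, so this count lies near the share over all genes. The cell cycle list had adjusted p = 0.0388, but adjusted p = 0.933 with an estimated correlation, and its call was lost without any 1 of 16 libraries (adjusted p 0.00506 to 0.211 over all of them), without clock hour 8, 11, 17, 20 or 23 (up to 0.440), by limma voom and on log2(TPM + 1).

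Lists of lipid storage and oxidation did not pass the test in JNK7b over the day. Lipid droplet markers were 3 higher and 3 lower of 23 measured, 4 and 4 adjusted over the list alone, adjusted p = 0.876, PPARα targets 2 higher and 6 lower of 32, 3 and 6, 0.0503, de novo lipogenesis genes 5 higher and 2 lower of 23, 6 and 3, 0.353 and female-biased genes 3 higher and 7 lower of 24, 5 and 7, 0.0903, in the same order. Unfolded protein response, endothelial, stellate cell and cholangiocyte lists had 0 members called by edgeR, DESeq2 or limma voom, with 2, 0, 1 and 4 members at an unadjusted p below 0.05 by edgeR, 2, 0, 1 and 4 by DESeq2 and 3, 0, 1 and 4 by limma voom. The median, mean and test differed in sign for the bile acid, gluconeogenesis, hepatokine, lipid droplet, JNK pathway, splicing regulator, unfolded protein response and NRF2 lists.

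The number of genes called depended on the hour. Against control, JNK7b had 596, 465, 608 and 738 genes called at 8, 11, 20 and 23 h, 36 at 14 h, 2 at 5 h and 0 at 2 and at 17 h (edgeR, 595 and 982 genes at an unadjusted p below 0.05 at 2 and 17 h). JNK7a against control ranged from 7 genes at 8 h and 36 at 11 h to 607 at 5 h, and JNK7b against JNK7a from 1 at 5 h to 791 at 20 h. The counts at 8 h include control 8 h replicate 3 (1 of 3 controls) and those at 5 h JNK7b 5 h replicate 2 (1 of 2 JNK7b libraries), which lie nearer to JNK7a than most of their groups. Without both, an alternative chosen after seeing the data, JNK7a against control had 3 genes at 8 h and JNK7b against control 325, with 1 control library fewer. JNK7b then has 1 library at 5 h, so its counts there are not read. With both sets of hours as an alternative chosen after seeing the data, 27 genes were called over 2, 5, 14 and 17 h (17 higher and 10 lower) and 2958 over 8, 11, 20 and 23 h (1487 higher and 1471 lower). The difference itself passed the test for 695 genes. Irf7 had a log2 fold change of 0.54 ± 0.12 over the first set (adjusted p = 0.0342) and 1.76 ± 0.11 over the second, a difference with adjusted p = 5.4e-07. Cyp2d12 had 0.34 ± 0.38 and 5.65 ± 0.37 (adjusted p = 5.5e-10 for the difference), Atp6v0e2 0.56 ± 0.23 and 3.93 ± 0.21 (adjusted p = 3.8e-11), and Igfbp2 0.88 ± 0.15 and 1.01 ± 0.14 (adjusted p = 0.801). Among the 10 lists called over the day, those of interferon response (adjusted p = 9.0e-06), cholesterol synthesis (adjusted p = 3.9e-22), male-biased genes (adjusted p = 1.9e-15) and CAR and PXR (adjusted p = 0.0285) were also called over 2, 5, 14 and 17 h alone. Cell cycle was called there in the opposite direction (adjusted p = 0.0329, lower). With an estimated correlation 0 of these 5 kept a call there (adjusted p = 0.545, 0.387, 0.485, 0.745 and 0.804). By edgeR 1 of 30 interferon genes was called (6 unadjusted, 4 adjusted over the list alone), with a median log2 change of 0.15, against 28 and 1.27 over 8, 11, 20 and 23 h. For cholesterol, male-biased, CAR and PXR and cell cycle genes 0 were called over 2, 5, 14 and 17 h (22, 13, 3 and 1 unadjusted, and 21, 8, 0 and 0 adjusted over the list alone). Over 8, 11, 20 and 23 h alone the male-biased list (6 genes higher and 4 lower, adjusted p = 0.122) and the CAR and PXR list (5 higher and 8 lower, adjusted p = 0.107) were not called. The cell cycle list was called higher over these hours (12 of 31 genes higher, median log2 0.65, camera adjusted p = 1.7e-05 with the preset correlation). Of all 35 lists, 11 passed over each set of hours, and with an estimated correlation 0 over the first and 1, interferon, over the second. Lists not called over the day were among them: PPARα targets over 8, 11, 20 and 23 h (9 lower and 3 higher, adjusted p = 0.0300, but 0.817 with an estimated correlation), and over 2, 5, 14 and 17 h de novo lipogenesis (higher, adjusted p = 0.00718, but 0.795) and female-biased genes (lower, adjusted p = 0.00518, but 0.745). Also of the 10 lists, those of Kupffer cells (adjusted p = 0.209), T and NK cells (adjusted p = 0.0928), B and plasma cells (adjusted p = 0.755), oxidative phosphorylation (adjusted p = 0.764) and amino acids (adjusted p = 0.306) were not called over 2, 5, 14 and 17 h.

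**Figure D2:**
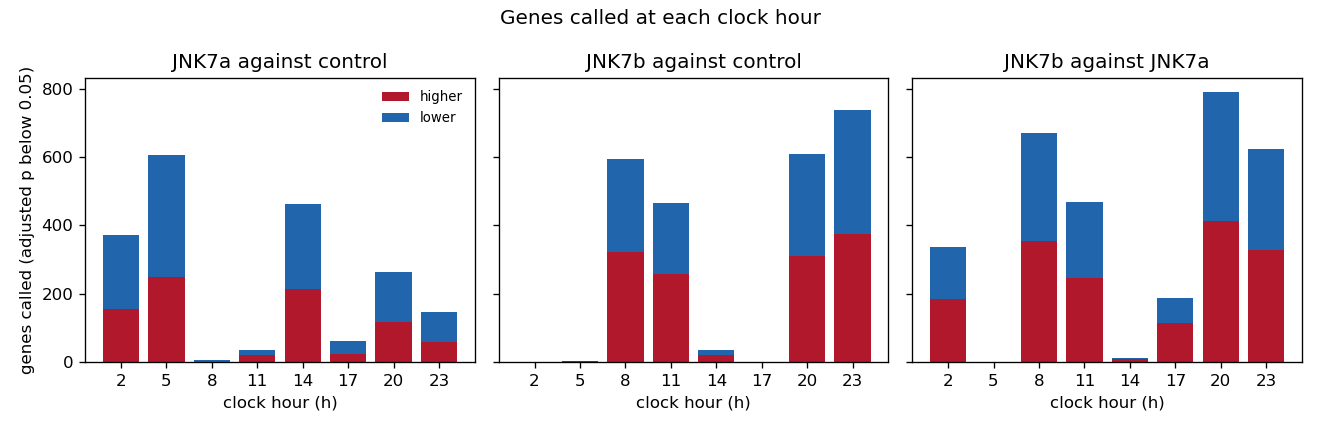
Genes called at each clock hour (horizontal axis) in the 3 comparisons, as stacked bars of genes higher and genes lower (vertical axis, number of genes). JNK7b against control has 596, 465, 608 and 738 genes at 8, 11, 20 and 23 h and at most 36 at the other hours.

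**Figure D3:**
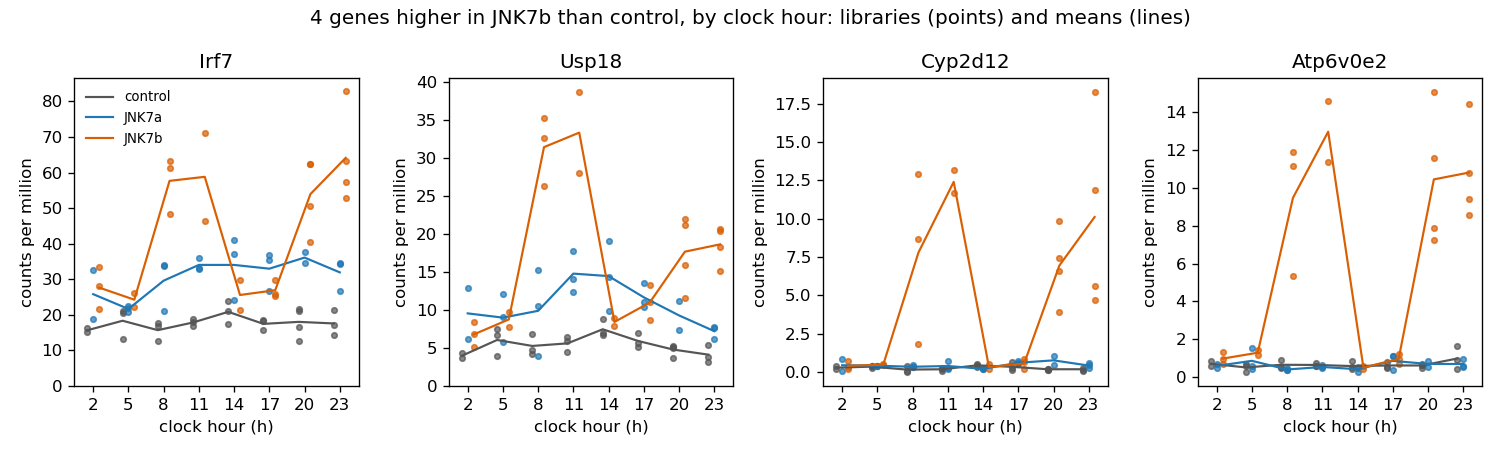
Expression in CPM (vertical axes) of Irf7, Usp18, Cyp2d12 and Atp6v0e2 by clock hour (horizontal axes); points are single libraries and lines join the group means, with groups shifted slightly sideways. Cyp2d12 and Atp6v0e2 are higher in JNK7b at 8, 11, 20 and 23 h, with Cyp2d12 at 8.96 ± 4.57 CPM there (SD, n = 13) and 0.455 ± 0.234 CPM at the other hours (n = 10).

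All counts come from the same edgeR test, and of 35 lists 10 passed camera with the preset correlation and 1, interferon response, with an estimated one. Without the 2 doubted libraries, 903 genes were higher and 862 lower, and 1628 of the 1935 calls remained.

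To compare the spliceoform groups directly, JNK7b libraries (n = 23) were set against JNK7a libraries (n = 22). The lipid droplet genes that were low in JNK7a were higher in JNK7b. Cidea was at 17.4 ± 13.8 CPM in JNK7b and 0.211 ± 0.191 CPM in JNK7a (SD; log2 6.28 ± 0.56, standard error, adjusted p = 3.4e-12). Cidec was at 55.9 ± 29.3 and 3.47 ± 2.59 CPM (log2 4.07 ± 0.34, adjusted p = 5.4e-13) and Plin4 at 35.6 ± 19.2 and 4.49 ± 1.92 CPM (log2 2.86 ± 0.22, adjusted p = 6.0e-14). Ntrk2, the gene of the neurotrophin receptor TrkB, was at 17.3 ± 11.7 against 1.63 ± 1.38 CPM (log2 3.54 ± 0.30, adjusted p = 7.2e-13). Ces2c, a carboxylesterase gene, was lower in JNK7b, at 24.4 ± 16.2 against 92.1 ± 28.2 CPM (log2 -1.98 ± 0.16, adjusted p = 6.3e-14).

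In total 1569 genes were higher and 1638 lower in JNK7b than in JNK7a, 212 and 102 of them at least 2-fold. Other large rises were those of Slc22a27 (log2 3.58 ± 0.32), Dusp8 (log2 3.44 ± 0.30) and Mogat1 (log2 3.38 ± 0.25). Hapln1, a hyaluronan link protein gene at 2.89 ± 3.07 against 0.30 ± 0.599 CPM, was called too. It was not called without JNK7b 14 h replicate 2 or 5 h replicate 1 (log2 3.07 and 2.88). Its lowest adjusted p over the fits that left out 1 library was 4.0e-07. Cyp2b13, at 1.26 ± 1.72 against 0.130 ± 0.185 CPM, lost its call by limma voom and on log2(TPM + 1). It was also not called without JNK7b 8 h replicate 3 (log2 2.87) or 11 h replicate 1 (log2 3.71). Its lowest adjusted p over such fits was 1.1e-04. A cell without counts can void the test in the Hapln1 fits and in the Cyp2b13 fit without 8 h replicate 3. Those fits therefore do not decide whether these calls rest on single libraries. The largest falls, beside Ces2c, were those of Obp2a (log2 -2.26 ± 0.36), the sulfotransferase gene Sult5a1 (log2 -2.22 ± 0.26) and Igkv1-135 (log2 -2.06 ± 0.39). Slc35f2 (log2 -1.94 ± 0.27), Cd4 (log2 -1.86 ± 0.31) and the adhesion receptor gene Adgrf1 (log2 -1.85 ± 0.35) fell as well, as did Hsd3b5 (log2 -1.81 ± 0.48, 57.1 ± 63.0 against 167 ± 80.8 CPM).

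Lipid lists were higher in JNK7b than in JNK7a. PPARα targets and fatty acid oxidation genes were higher in 20 and lower in 1 of 32 cases (22 and 1 adjusted over the list alone), including Acot2 (log2 1.52 ± 0.16) and the fatty acid hydroxylase gene Cyp4a14 (log2 1.51 ± 0.16). The PPARα list had camera adjusted p = 1.2e-14, but adjusted p = 0.140 with an estimated correlation. Lipid droplet markers were higher in 17 and lower in 2 of 23 cases (18 and 3 adjusted over the list alone). The lipid droplet list had adjusted p = 2.4e-12, but adjusted p = 0.0786 with an estimated correlation. De novo lipogenesis genes were higher in 11 and lower in 1 of 23 cases (16 and 2 adjusted over the list alone), including the acetyl-CoA carboxylase gene Acacb (log2 1.13 ± 0.16), Elovl5 (log2 0.91 ± 0.12) and the desaturase gene Fads2 (log2 0.54 ± 0.10). The lipogenesis list had adjusted p = 1.0e-05, but adjusted p = 0.549 with an estimated correlation.

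Sex-biased, bile acid and stress lists moved apart as well. Male-biased genes were lower in 20 and higher in 2 of 29 cases (21 and 2 adjusted over the list alone), including Sult5a1 and Keg1 (log2 -1.13 ± 0.13). The male-biased list had adjusted p = 2.9e-09, but adjusted p = 0.549 with an estimated correlation. Female-biased genes were higher in 13 of 24 cases (13 higher and 1 lower adjusted over the list alone), including Hao2 (log2 3.11 ± 0.35). The female-biased list had adjusted p = 1.1e-08, but adjusted p = 0.140 with an estimated correlation. Bile acid genes were lower in 12 and higher in 3 of 23 cases (12 and 3 adjusted over the list alone), with Cyp2c70 lower (log2 -1.07 ± 0.12). The bile acid list had adjusted p = 6.3e-04, but adjusted p = 0.140 with an estimated correlation. Unfolded protein response genes were lower in 10 of 26 cases (11 adjusted over the list alone), including Xbp1 (log2 -0.43 ± 0.06). The unfolded protein list had adjusted p = 0.00164, but adjusted p = 0.549 with an estimated correlation, and its call was lost without clock hour 2 (adjusted p = 0.0601, from 8.4e-06 over the alternatives). AP-1 and immediate early genes were higher in 7 and lower in 1 of 25 cases (7 and 1 adjusted over the list alone), including Jun (log2 1.5 ± 0.18) and Jund (log2 0.63 ± 0.07). The AP-1 list had adjusted p = 0.00718, but adjusted p = 0.549 with an estimated correlation, and its call was lost on log2(TPM + 1) (adjusted p = 0.0507, from 7.8e-05 over the alternatives).

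Interferon response genes were higher in 14 and lower in 2 of 30 cases (17 and 2 adjusted over the list alone), including Irf7 (log2 0.36 ± 0.08). The sign of Irf7 was reversed over 2, 5, 14 and 17 h alone. The interferon list had adjusted p = 5.2e-04, but adjusted p = 0.549 with an estimated correlation, and its call was lost without clock hour 8 (adjusted p = 0.0735, from 1.0e-07 over the alternatives). Over 2, 5, 14 and 17 h alone 4 interferon genes were called lower and the list had adjusted p = 3.2e-04 (lower), but adjusted p = 0.550 with an estimated correlation. Cell cycle genes were higher in 8 of 31 cases (8 adjusted over the list alone), including the mitotic kinase gene Cdk1 (log2 1.34 ± 0.22) and the replication helicase gene Mcm5 (log2 0.62 ± 0.14). The cell cycle list had adjusted p = 0.00336, but adjusted p = 0.609 with an estimated correlation. Amino acid and urea genes were lower in 10 and higher in 1 of 24 cases (10 and 1 adjusted over the list alone). The amino acid list had adjusted p = 0.00905, but adjusted p = 0.634 with an estimated correlation, and its call was lost without JNK7a 2 h replicate 2 (adjusted p = 0.0671, from 0.00110 over the fits that left out 1 library). Extracellular matrix genes were higher in 5 and lower in 1 of 24 cases (6 and 1 adjusted over the list alone). The extracellular matrix list had adjusted p = 0.0207, but adjusted p = 0.668 with an estimated correlation, and its call was lost without JNK7b 2 h replicate 3 (adjusted p = 0.0963) or 8 h replicate 3 (adjusted p = 0.0618), from 0.00268 over these fits, and also lost by limma voom, on TPM and without clock hour 8 or 17 (up to 0.127). Periportal markers were lower in 8 and higher in 1 of 21 cases (8 and 1 adjusted over the list alone), with Alb lower (log2 -0.28 ± 0.06). The periportal list had adjusted p = 0.0253, but adjusted p = 0.634 with an estimated correlation, and its call was lost without JNK7a 2 h replicate 2 (adjusted p = 0.217) or JNK7b 8 h replicate 3 (adjusted p = 0.0542), from 8.0e-04 over these fits, or without clock hour 8 or 14 (up to 0.0612). Oxidative phosphorylation genes were higher in 7 and lower in 1 of 37 cases (7 and 1 adjusted over the list alone). The oxidative phosphorylation list had adjusted p = 0.0390, but adjusted p = 0.828 with an estimated correlation, and its call was lost without any 1 of 17 libraries (adjusted p 0.00508 to 0.127 over all of them), without clock hour 2, 5 or 14 (up to 0.503) and with the additive design.

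Of 35 lists, 14 passed camera with the preset correlation and 0 with an estimated one. Among the lists that did not pass, B and plasma cell markers had 0 of 13 called by edgeR (2 unadjusted), 1 by DESeq2 (2 unadjusted) and 0 by limma voom (2 unadjusted), adjusted p = 0.102. The median, mean and test differed here in sign for the core clock, splicing regulator, acute phase, CAR and PXR, AhR, heat shock, neutrophil, endothelial, cholangiocyte and adipocyte lists. On the deposited TPM 2071 genes were higher and 708 lower, a share of 74.5% higher against 48.9% in the counts. The median log2 change over all genes was 0.039 in TPM and -0.0054 in the counts. Without the 2 doubted libraries 1631 genes were higher and 1587 lower, and 2982 of the 3207 calls remained. Over 2, 5, 14 and 17 h alone 757 genes were higher and 558 lower, and over 8, 11, 20 and 23 h 1578 and 1544, as alternatives chosen after seeing the data, with 1062 genes past the test of the difference. Of the 14 lists, those of cell cycle (adjusted p = 0.615), AP-1 (adjusted p = 0.401), amino acids (adjusted p = 0.611), extracellular matrix (adjusted p = 0.513), bile acids (adjusted p = 0.319) and periportal markers (adjusted p = 0.110) were not called over the first set. Those of the unfolded protein response (adjusted p = 0.267), oxidative phosphorylation (adjusted p = 0.111) and periportal markers (adjusted p = 0.0612) were not called over the second. Some lists not called over the day were called over the first set by camera with the preset correlation. Among them were B and plasma cells (4 of 13 genes lower, adjusted p = 4.0e-06) and T and NK cells (1 of 16 lower, adjusted p = 1.0e-04), both lower. With an estimated correlation 1 of 35 lists passed over that set.

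The changes of JNK7a and JNK7b against the shared control libraries overlapped. Both comparisons called 358 genes higher and 372 lower, and 148 in opposite directions, where independent lists of these sizes would share 91.7 and 109. The correlation of the log2 fold changes across 14398 genes, which are not independent replicates, was 0.413, and unchanged groups simulated against the same controls gave 0.479. The covariance was 0.0495 against 0.0109 in the simulation, a difference of 0.0387. With the control libraries split between the comparisons, the covariances were 0.0606 and 0.0578, above the 0.0495 with shared controls. The difference of 0.0387 is therefore not read as a measure of the part free of shared controls. The correlations in the splits were 0.353 and 0.322, with 170 and 188 genes higher and 118 and 123 lower in both. Independent lists would share 37.2 and 41.4 higher and 29.5 and 32.2 lower, and 52 genes were called in opposite directions in each split.

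The study design asks how circadian gene expression differs between the groups, so a 24 h cosine was fitted to each gene in each group. The core clock cycled in all 3 groups. Arntl, the gene of the clock activator BMAL1, peaked at 3.68 ± 0.40 h in control (standard error, n = 24), 4.11 ± 0.34 h in JNK7a (n = 22) and 4.13 ± 0.32 h in JNK7b (n = 23). Nr1d1, which encodes the clock repressor REV-ERBα, peaked at 12.8 ± 0.30, 13.5 ± 0.30 and 13.4 ± 0.22 h. Dbp, a clock output transcription factor gene, peaked at 15.9 ± 0.29, 16.5 ± 0.34 and 16.5 ± 0.20 h. Of the 19 core clock genes, all were called rhythmic in each group except Rora, which was not called in control (adjusted p = 0.0760) or JNK7b (adjusted p = 0.609).

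**Figure D4:**
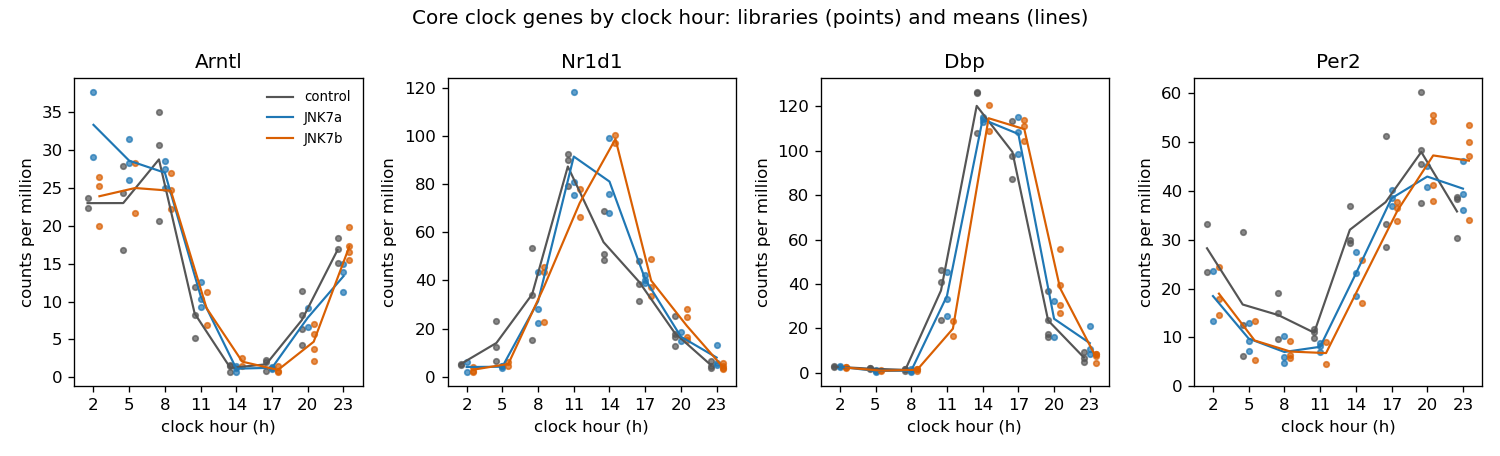
Expression in CPM (vertical axes) of Arntl, Nr1d1, Dbp and Per2 by clock hour (horizontal axes); points are single libraries and lines join the group means. The 3 groups peak at similar hours, for example Arntl at 3.68, 4.11 and 4.13 h.

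Over all genes, 3405 were rhythmic in control, 3774 in JNK7a and 2445 in JNK7b with a 24 h cosine, but 3624, 3467 and 4249 with 24 h and 12 h cosines together, so the order of the groups depends on the model. Of these 1444 were rhythmic in all 3 groups and 2654 in exactly 1, but these are counts past a threshold and do not show that rhythms differed. The test of the difference itself called 1 gene between JNK7a and control, the acyltransferase gene Acnat2 (adjusted p = 0.00360), which peaked at 23.9 ± 0.54 h with a log2 amplitude of 0.88 ± 0.13 in control and at 4.41 ± 0.42 h with an amplitude of 1.3 ± 0.14 in JNK7a. It called 0 genes between JNK7b and control and 0 between JNK7b and JNK7a with edgeR, against 803, 740 and 772 genes at an unadjusted p below 0.05 in the 3 comparisons. DESeq2 called 2, 1 and 0 (881, 824 and 856 unadjusted) and limma voom 1, 0 and 0 (935, 786 and 1000 unadjusted). The 0 genes of the JNK7b comparisons hold for the 24 h cosine alone. With an 8-level factor of hour, 248 genes differed between JNK7b and control and 315 between JNK7b and JNK7a, and with 24 h and 12 h cosines together 273 and 372. Both models also take up the split of JNK7b between the sets of hours, so these counts do not tell a difference of rhythm from that split. The Acnat2 call was lost with an 8-level factor of hour (adjusted p = 0.157), with 24 h and 12 h cosines together, and without clock hour 5, 17 or 20. It was lost with the replicate block too.

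Among the core clock genes, 0 differences of rhythm were called by edgeR over all genes or adjusted over the list alone, with 1, 3 and 2 genes at an unadjusted p below 0.05 in JNK7a against control, JNK7b against control and JNK7b against JNK7a. The median difference of peak hour over the 19 genes was 0.480 h, 0.543 h and 0.0926 h in these comparisons, and the median difference of log2 amplitude 0.22, 0.06 and -0.12. Per2 had a log2 amplitude of 0.99 in control, 1.46 in JNK7a and 1.53 in JNK7b. Averaged over the day, Per2 was lower in JNK7a (log2 -0.41 ± 0.12, adjusted p = 0.0121, lost without clock hour 8) and in JNK7b (log2 -0.43 ± 0.13, adjusted p = 0.0142, lost without clock hour 8 or 11), and Hlf in JNK7b (log2 -0.20 ± 0.05, adjusted p = 0.00287) and in JNK7a (log2 -0.15 ± 0.05, adjusted p = 0.0210, lost without JNK7a 2 h replicate 2, without clock hour 2 or 20 and with the additive design). Read back from 16 core clock genes, the clock hour of 68 of 69 libraries lay within 3 h of the label, with a median distance of 0.50 h. A gene whose rhythm of log2 amplitude 0.5 was removed in simulated JNK7b libraries was called in 56% of cases against control and at amplitude 1 in 92%. The simulated genes were independent and otherwise flat, and those given a rhythm had a mean above 1 CPM. The hour-set pattern of JNK7b was not simulated, so the shares in the real libraries may be lower.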

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

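The tests of hour sets, of a batch shared by the groups, of a separate cohort and of the hepatocyte share were chosen only after the result was seen; the others were not.

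The difference between JNK7b and control differed between 8, 11, 20 and 23 h and the other hours for 695 genes, and the difference between JNK7b and JNK7a for 1062; these hours were picked from the data, and among all 35 ways to split the 8 hours into 4 and 4 the next highest counts were 144 and 322. A shift of the clock or wrong hour labels are argued against by the core clock genes, which placed the JNK7b libraries of those hours a median of 0.25 h from their labels, and a batch of those hours shared by the groups by the 349 genes that differ 2-fold between the sets within JNK7b, whose median log2 difference was 1.38 there but 0.0721 in control and -0.0072 in JNK7a. For a chromosome segment of another strain, 42.6% of 343 such genes with a position had another within 1 Mb. In 10000 random draws of tested genes the median was 39.4%, and the middle 95% ran from 32.9% to 45.8%. As a set these genes were not clustered beyond the random draws. A segment that holds few of them would not move this share, so such a segment stays open. A separate cohort of JNK7b mice stays open, because 0 of those libraries carry a label that ties them to one, and so does an effect of JNK7b that depends on the hour, as a hypothesis. Of the 27 genes called against control at the other hours, 22 were called in both sets, all in the same direction.

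A score over 100 genes had 0 at the control mean and 1 at the JNK7a mean, both over all hours and not matched by hour. Control 8 h replicate 3 stood at 0.647, where the next control library, 8 h replicate 2, had 0.312. JNK7a libraries lay between 0.701 and 1.34. The other control libraries of 8 and 11 h stood at 0.133 to 0.312, above the control median of -0.0642. The score therefore does not separate the hour from the label. JNK7b 5 h replicate 2 stood at 0.744, among 6 JNK7b libraries above 0.5. JNK7b 8 h replicate 1 at 0.734 also lies inside the JNK7a range, and JNK7b 23 h replicates 4 and 3 at 0.678 and 0.651 lie above control 8 h replicate 3. These 3 JNK7b libraries were kept in the fit without the doubted libraries. A swap of labels between control and JNK7a is argued against, since the lowest JNK7a library, at 0.701, leaves no partner on the control side. A single wrong label may apply to JNK7b 5 h replicate 2, whose score lies inside the JNK7a range as a JNK7a library's would. Its Cidec (7.15 CPM), Plin4 (5.73 CPM), Igfbp2 (358 CPM) and Mapk9 (36.5 CPM) lie inside that range too. The score of JNK7b 8 h replicate 1 does so as well, but the other JNK7b libraries above 0.5 were all of 8, 11 or 23 h. At 8, 11, 20 and 23 h JNK7b Cidec was at least 13.6 CPM, above the JNK7a maximum of 10.9 CPM. Among JNK7b libraries of 2, 5, 14 and 17 h the next highest score was 0.185. A wrong label of JNK7b 5 h replicate 2 stays open. It may also apply to control 8 h replicate 3, whose score at 0.647 falls just under that range, by less than the spread of those libraries, so that this value decides nothing, while its Mapk9 of 14.1 CPM, below the 28.9 to 47.3 CPM of JNK7a, is a value of neither group. An animal whose liver differed from its group also stays open and was not tested.

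Some immune cell markers were higher against control: of 23 Kupffer, 16 T and NK and 13 B and plasma cell markers 3, 9 and 4 were called higher in JNK7a, and 6, 4 and 3 in JNK7b, with 1 T and NK marker lower. Over all 14398 genes 1391 were called higher in JNK7a and 949 in JNK7b, so the Kupffer count of JNK7a lies near that share. The immune cell lists passed limma camera with the preset correlation, but not with an estimated one (adjusted p = 0.148 to 0.852), and in JNK7b not over 2, 5, 14 and 17 h alone. A lower share of hepatocytes would raise the markers of every other cell type alike. Over 52 immune genes the mean log2 change exceeded that of 39 endothelial and stellate cell genes by 0.615 (standard error over genes 0.085) in JNK7a and by 0.427 (0.075) in JNK7b. These errors take the genes as independent and do not measure the spread between libraries. The mean of the 39 genes itself was -0.024 in JNK7a and 0.044 in JNK7b. These means argue against a lower share as the only account, without a test over libraries. Of the most abundant markers, Igkc of plasma cells was at 72.6 CPM in JNK7a, 51.5 CPM in JNK7b and 14.8 CPM in control, and Mpeg1 of macrophages at 61.1, 86.8 and 49.3 CPM; 2 of the 23 Kupffer cell markers are in another list too. More immune cells, or more transcripts in the same cells, may each account for this and were not told apart.

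Other splits of the samples bear on whether chance alone gives such counts. With group labels permuted within clock hours and only the groups compared in the fit, 1 of 100 splits, the real one, gave as many genes for JNK7a against control (2942, highest other 62), for JNK7b against control (1858, highest other 4) and for JNK7b against JNK7a (3012, highest other 276). Chance alone is thus unlikely for these, if the libraries of an hour are separate animals. A cohort tied to a group would give the same result. With hours permuted within a group, 1 of 100 gave as many rhythmic genes in control (3280, highest other 489), JNK7a (3440, highest other 56) and JNK7b (2017, highest other 23). For the 1 difference of rhythm between JNK7a and control chance is not excluded: 7 of 100 splits gave at least as many, up to 321, and the cause of that high count was not found. For JNK7b against control and against JNK7a the real count was 0, which all 100 splits reach whatever the data (highest other 117 and 1), so nothing is tested there.

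Control at 20 h and JNK7b at 20 and 23 h had 4 libraries each. Over several measures these gave 117 sets of 4 values, in which 7 values of named genes stood far from the other 3. Chance alone marks about 5% of independent sets with normal spread. The sets share the same libraries and hold unlogged CPM, so that share is only a rough guide. At 20 h in control these were Dnaic1 in replicate 3 (0.254 CPM, the others at 0), Ighg2b in replicate 2 (1.10 CPM, the others 0.392 to 0.492), Cyp2b13 in replicate 1 (10.3 CPM, the others 0.441 to 1.44) and Cfd in replicate 4 (17.8 CPM, the others 3.37 to 5.43). At 20 h in JNK7b they were Dusp8 in replicate 2 (3.46 CPM, the others 1.80 to 1.92) and Atp6v0d2 in replicate 3 (2.52 CPM, the others 0.0944 to 0.495), and at 23 h in JNK7b Igkv10-96 in replicate 2 (8.19 CPM, the others 0.161 to 0.886). The difference of rhythm between JNK7a and control was called for 1 gene, Acnat2.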

How the results depend on the processing

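The fits of the hour sets, with their estimated correlation, without the doubted libraries and of the 12 h component alone were chosen only after the result was seen; the other alternatives were not. Of 339 called named genes, 303 kept their call and direction in every fit that left out 1 library, 257 in every other alternative set beforehand and 126 in every added one, where 15 reversed; of 38 called lists the counts were 31, 28 and 21, with 4 reversed. Leaving out 1 library in turn gave 1247 to 1446 genes higher and 1449 to 1647 lower in JNK7a against control, 815 to 1031 and 811 to 1036 in JNK7b against control, 1350 to 1646 and 1394 to 1703 in JNK7b against JNK7a, with 14 to 17, 8 to 12 and 12 to 16 lists. Rhythmic genes ranged from 3027 to 3664 in control, 3389 to 4088 in JNK7a and 2192 to 2657 in JNK7b, and differences of rhythm stayed at 1, 0 and 0. Depth limits low genes most, and the cause of the shifts below was not tested except where given.

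Among the alternatives set beforehand, no filter gave 603 genes lower in JNK7b against control and 426, 426 and 443 differences of rhythm over 29850 genes, of which 18, 18 and 17 were tested with the filter, so most are genes too low for the filter. A mean of at least 1 CPM gave 1 difference of rhythm between JNK7b and JNK7a. DESeq2 gave 2 and 1 against control in JNK7a and JNK7b. On log2(TPM + 1) JNK7a against control had 703 higher and 2410 lower genes and JNK7b against JNK7a 708 lower; on log2(TPM + 0.1) these were 706, 2448 and 706. The 8-level factor of hour gave 248 and 315 differences of rhythm for JNK7b against control and against JNK7a. The 24 h and 12 h cosines together gave 3624 rhythmic genes in control, 3467 in JNK7a and 4249 in JNK7b, and 0, 273 and 372 differences of rhythm. Both models also take up the split of JNK7b between the sets of hours. Without clock hour 5 there were 0 differences of rhythm in JNK7a against control; without hour 8, 1 in JNK7b against control and 1 against JNK7a; without hour 11, 553 genes lower in JNK7b against control and 2 differences in JNK7a against control; without hour 17, 2508 rhythmic genes in JNK7a and 0 differences from control; without hour 20, 611 genes lower in JNK7b against control, 0 differences in JNK7a against control and 1 in JNK7b against JNK7a; without hour 23, 618 genes higher and 531 lower in JNK7b against control and 2 differences in JNK7a against control. Fewer libraries entered each of these fits.

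The replicate block gave 0 differences of rhythm in JNK7a against control and moved no other of these counts by over 1.5 times. It ended the list calls of amino acids and cell cycle in JNK7b against control and of extracellular matrix and oxidative phosphorylation in JNK7b against JNK7a. The difference of rhythm of Acnat2 had adjusted p = 0.0503 with the block. The numbers do not pair the samples: over 62 same-numbered pairs the median correlation of deviations was -0.00856 and the highest 0.0888, while pairs of other numbers reached a median of 0.00531, so the block is only a check.

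Of the added fits, the 12 h component alone gave 78 rhythmic genes in control, 15 in JNK7a and 1958 in JNK7b, and 0, 450 and 579 differences. This component also takes up the split between the 2 sets of hours, which repeat with a 12 h period, so a 12 h rhythm in JNK7b is not told apart from that split. Hours 2, 5, 14 and 17 alone gave 913 genes higher in JNK7a against control, 17 higher and 10 lower in JNK7b against control, and 757 and 558 in JNK7b against JNK7a; hours 8, 11, 20 and 23 alone gave 572 and 684 in JNK7a and 1487 higher in JNK7b against control. At 2, 5, 14 and 17 h alone the sign reversed in JNK7b against control for Tef (0.013), Agpat2 (0.015), Mmp12 (-0.10), Sult5a1 (0.30), Hspa1b (-0.021), Wfdc21 (0.082) and Alas2 (0.042), in log2, and for the lists of amino acids (adjusted p = 0.306) and cell cycle (adjusted p = 0.0329, lower, but 0.804 with an estimated correlation), and in JNK7b against JNK7a for Baat (0.015), Pfkfb1 (0.064), Rbfox2 (-0.070), Irf7 (-0.11), Usp18 (-0.35), Mpeg1 (-0.090), Cd9 (-0.022) and the interferon list (adjusted p = 3.2e-04, lower, but 0.550 with an estimated correlation). At 8, 11, 20 and 23 h alone it reversed for Klrb1c in JNK7a against control (-0.27) and, beside the 15, for Igha in JNK7b against JNK7a (1.08), which was not called over the day, and for oxidative phosphorylation (adjusted p = 0.111).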

Other observations

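The genes below that differ between hour sets within JNK7b were chosen after their values were seen, and the test of those sets was chosen only after the result was seen.

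Within JNK7b, several genes differed between the libraries of 2, 5, 14 and 17 h and those of 8, 11, 20 and 23 h. The noncoding RNA genes Rian (chromosome 12, 109603940 to 109661716, mm10) and Meg3 (chromosome 12, 109541001 to 109571726), which neighbour each other in an imprinted region, were at 0.215 ± 0.398 and 0.400 ± 0.577 CPM in the 10 libraries of the first set (SD) and at 12.1 ± 5.30 and 12.3 ± 6.45 CPM in the 13 of the second. The extracellular matrix gene Itih5 rose from 10.6 ± 2.98 to 59.4 ± 13.9 CPM and the interferon-induced gene Ifi27 from 113 ± 19.1 to 297 ± 55.1 CPM between the sets, while Spp2 fell from 57.4 ± 7.80 to 22.5 ± 7.29 CPM. In control and JNK7a, Rian stayed at 0.295 and 0.350 CPM and at 1.27 and 1.79 CPM in the same sets. Between the sets 2746 genes were called in JNK7b, 267 in control and 12 in JNK7a (edgeR).

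Some members of pathways outside the main patterns also changed. In JNK7a the aldehyde dehydrogenase gene Aldh3a2 was lower (log2 -0.59 ± 0.07, adjusted p = 1.8e-08) and the pericentral gene Cyp1a2 higher (log2 1.14 ± 0.12, adjusted p = 3.0e-10). In JNK7b the ammonium transporter gene Rhbg was higher (log2 1.06 ± 0.15, adjusted p = 9.3e-07) and Cyp2e1 lower (log2 -0.50 ± 0.08, adjusted p = 1.1e-05), while the small heat shock protein gene Hspb1 was higher (log2 0.97 ± 0.12, adjusted p = 6.7e-08). Over 2, 5, 14 and 17 h alone these JNK7b differences were not called (adjusted p = 0.492, 0.853 and 0.489, edgeR).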
